A study of Mus musculus with 2 samples.

How the data were processed

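Total RNA from serum-starved mouse embryonic fibroblasts (MEFs) of 2 genotypes, p27delta51 and wild type, was labelled with biotin and hybridised to Affymetrix expression arrays, per the labels' protocols. Each genotype was represented by 1 array. Cells had been cultured in 10% fetal bovine serum and were kept without serum for 72 h. Per the labels' protocols, only RNA that passed integrity and purity limits was used.

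The deposited value table holds a signal intensity on a linear scale for each of 45101 probe sets on each array. RMA and affy are named per the submitters' processing notes, without a version. RMA gives log2 values, whereas the deposited intensity values are linear, carry 1 decimal, include a few zeros and have a trimmed mean of 150.0 on both arrays after removal of 2% of the values at each end. That is the form of signals from the Affymetrix MAS5 algorithm, and which program wrote them is not given in the sources used here. The design had assumed RMA values, on a log2 scale or not, so log2 was taken of the signals, with the smallest step, 0.1, standing in for a signal of 0. Per the file headers, a second deposited table gives the authors' log2 signal ratio of p27delta51 over wild type for each probe set, a change call and a change p-value. In that table the authors' p-value lies near 0 for an increase and near 1 for a decrease, and it compares the 2 arrays, not the genotypes. Over all probe sets, the authors' log2 ratio correlated with the log2 ratio of the value table at a Pearson r of 0.943, computed across probe sets, which are not independent replicates.

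Probe sets were named through the platform annotation supplied with the series, and symbols were updated by gene identifier to the GRCm38.p6 gene table. Of the probe sets, 34945 carried 1 gene symbol (34741 of them were found in the gene table), 932 carried several, 9160 had no name here and 64 were controls. Only probe sets with 1 symbol were used. Chromosomes and gene order come from the GRCm38.p6 gene table. All sample columns of the value table were used, so the number of unused columns was 0.

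For each of 18193 named genes, the probe set with the highest mean signal over both arrays was taken. Genes whose mean was at or above the median of all probe sets' means (22.2) were kept, which left 11159 genes. The choice of the linear mean for this ranking was made after the values were seen, so a ranking on mean log2 signals was run as an alternative. A control floor was set for each array as the highest signal among 27 control probe sets for bacterial transcripts outside the hybridisation controls. It was 14.8 for p27delta51 and 11.8 for wild type. Where the dimmer array lay at or below its floor, the fold was computed against the floor and is given as at least that size. Signals above the floor were found for 58.6% of probe sets on the p27delta51 array and 62.6% on the wild type array. The number of arrays limits the precision. With 1 array per group no test was made, no SD can be given, and no difference has a replicate check.

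The gene lists and the rule for named genes were fixed before the data were examined. Named genes were the 12 kept genes with the largest positive and the 12 with the largest negative log2 difference, leaving out unnamed transcripts and genes with another bright probe set of opposite sign. Added to these were Cdkn1b, Actb, Gapdh, the sex-linked genes and, for each list, up to 2 members with the largest difference in each direction. For each of 43 lists the median log2 difference of the kept members was set against 10000 random lists of the same size, drawn from kept genes matched on mean signal in 20 bins with seed 1. A list was called apart when its percentile was at or below 0.5 or at or above 99.5, which takes in about 1% of independent lists by chance. Lists with fewer than 5 kept members received no percentile, and the result of 1 list is not reported here. The spread between probe sets of a gene, the only repeat measurement here, is technical. Its median SD was 0.23 on the log2 scale over 5316 genes with at least 2 bright probe sets.

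The steps were tested on simulated data built on the 11159 kept genes, with normal noise drawn independently for each gene at the spread of the real differences. The 2-fold threshold was passed by 50.5% of genes with a simulated 2-fold shift, by 91.0% of genes with a simulated 4-fold shift and by 10.7% of unshifted genes. A 2-fold shift lies on the threshold, so the first share follows by construction. The other shares follow from the chosen noise, whose spread takes in any real differences between the arrays. They therefore give no detection rate or false-call rate for these data. Of 40 simulated lists shifted by 0.5 on the log2 scale, 24 were called apart in the right direction, and 0 unshifted lists were called. Because the noise was independent between genes, this says nothing about false calls for lists whose genes vary together.

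Alternatives fixed beforehand were no brightness filter, an upper-quartile filter, the mean of all probe sets of a gene, a loess correction (span 0.3), median centring, quantile normalization, the authors' log2 ratio, log2 of the signal plus 32, thresholds of 1.5-fold and 3-fold, and random lists not matched on signal. Alternatives added after seeing the data were signals raised to the control floor, ranking on mean log2 signals, and other filters for the spread between probe sets. Intervals for chromosome medians are 95% bootstrap intervals over genes and cover the spread between genes only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Probe sets without a name or with several genes were left out of the gene comparison.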

Results

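Transcript levels were measured in quiescent mouse embryonic fibroblasts (MEFs), connective tissue cells grown out of mouse embryos, that carried the p27delta51 allele or were wild type. Cdkn1b encodes p27, an inhibitor of cyclin-dependent kinases (CDKs) that holds cells out of the division cycle. The p27delta51 allele is known for lacking the amino-terminal, CDK-inhibiting part of the protein. Cells of both genotypes were starved of serum for 72 h, and RNA of each was hybridised to 1 array. The median signal over 45101 probe sets was 22.2 on the p27delta51 array and 21.2 on the wild type array. The comparison asks how expression in quiescent p27delta51 cells differs from that in quiescent wild type cells. No difference below has a replicate check, and all values describe these 2 arrays. With 1 array per genotype, the design does not separate the allele from other differences between the cultures, and the arrays also differed in sex-linked, Hox and Cdkn2a transcripts and in chromosome medians.

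Cdkn1b itself was read by 2 probe sets that went opposite ways. The dimmer probe set gave a signal of 1.6 in p27delta51 and 62.0 in wild type, at least 4.19-fold lower in p27delta51. The brighter probe set gave 1016 in p27delta51 and 542 in wild type, a log2 difference of 0.91. In the authors' deposited table the log2 ratios were -4.8 and 0.6. Where each probe set lies relative to the deleted part was not established here, and a probe set outside that part checks nothing about the allele.

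Transcripts of DNA replication, mitosis and the interferon response were higher in p27delta51 cells, and those of the contractile apparatus, the imprinted genes and the secretory stress response were lower. Of 11159 kept genes, 1200 (10.8%) were at least 2-fold higher in p27delta51 and 979 (8.77%) at least 2-fold lower. Differences of at least 10-fold were found for 92 genes higher and 144 genes lower in p27delta51. The median log2 difference of all kept genes was 0.079, with quartiles at -0.33 and 0.51. Log2 signals of the 2 arrays correlated at a Pearson r of 0.808 across kept genes, which are not independent replicates. Among 900 of the 2-fold genes with at least 2 bright probe sets, 850 (94.4%) had all of these on the same side. In the authors' deposited table, 88.8% of the 2-fold higher genes carried an increase or marginal increase call and 89.5% of the 2-fold lower genes a decrease or marginal decrease call.

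**Figure D1:**
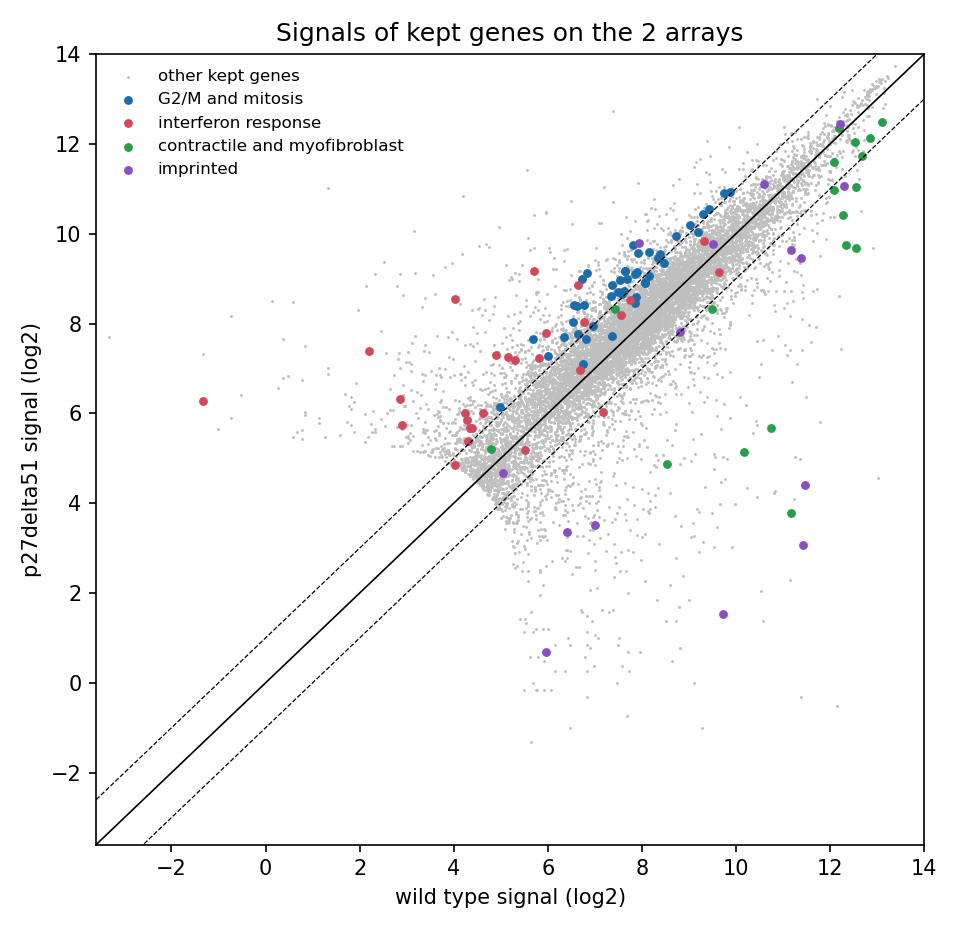
Signals of the 11159 kept genes on the log2 scale, wild type on the x axis and p27delta51 on the y axis, 1 point per gene, with members of 4 gene lists in colour. The solid line marks equal signals and the dashed lines a 2-fold difference; all 44 kept mitosis genes lie above the solid line.

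The 12 genes with the largest log2 difference in each direction, except Igfbp2, were bright on 1 array and at the control floor on the other. Signals under the floor set their rank, so the bounds for some are smaller than folds measured above the floor elsewhere. Folds whose dimmer signal is above the floor but within 3 times of it rest on a signal near background and are approximate, as for Xist, Arhgdib, Osr2, Fst, Sfrp1, Bambi, Dll1, Egln3 and Nr4a2. Crabp2, which encodes a retinoic acid carrier, gave 4517 in p27delta51 and 2.6 in wild type, at least 383-fold higher. Hoxd13, a transcription factor gene of the distal limb, gave 2079 against 2.5, at least 176-fold higher. Shisa2 was at least 90.9-fold and Evi2a at least 55.9-fold higher in p27delta51. Ebf3 gave 546 against 5.0, with a log2 ratio of 4.5 in the authors' deposited table. Tbx4, known for its role in hindlimb development, was at least 30.5-fold higher, and Amph, Dmp1, Pi16 and Sall1 were at least 24.4-fold, 17.6-fold, 17.2-fold and 13.6-fold higher. Sparcl1 and Oasl2 were at least 7.20-fold and 6.61-fold higher. In the other direction, Igfbp2, an insulin-like growth factor binding protein gene, gave 23.7 in p27delta51 and 8305 in wild type. Cthrc1 gave 0.7 against 4538, at least 307-fold lower, and Cnmd, a cartilage gene, was at least 180-fold lower. Cyp1b1, Ptgis, Pdzrn3, Tmem178, Pgm5 and Fbxl7 were at least 154-fold, 102-fold, 99.4-fold, 41.7-fold, 37.1-fold and 13.9-fold lower. The remaining genes of this group were the imprinted Peg3, Meg3 and Rian, at least 186-fold, 57.3-fold and 26.9-fold lower.

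Genes of DNA replication and genes of mitosis were higher in p27delta51 as groups. Of 38 kept genes of the G1/S and DNA replication list, which are controlled by E2F transcription factors, 20 were at least 2-fold higher, 1 was at least 2-fold lower and 17 lay between. Their median log2 difference was 1.06, above all 10000 matched random lists. Cdt1, a replication licensing gene, gave 1377 in p27delta51 and 271 in wild type, 5.09-fold higher, and Prim1, a primase subunit gene, was 3.61-fold higher. Ccne1, the cyclin E1 gene, was 3.40-fold lower, against a log2 ratio of -0.9 in the authors' deposited table, and Rrm1 gave 719 against 1077. All 44 kept genes of the G2/M and mitosis list were higher in p27delta51, 33 of them at least 2-fold, with a median of 1.18 that also lay above all 10000 random lists. Cenpf and Kif23, which act on kinetochores and in cytokinesis, were 4.87-fold and 4.86-fold higher.

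Genes for cyclins, CDKs, CDK inhibitors and pocket proteins did not stand apart as a list. Of 29 kept members, 3 were at least 2-fold higher and 5 at least 2-fold lower. Their median was 0.29, above 9517 of 10000 random lists, while their mean, with signals below the floor raised to it, was -0.21. E2f8 gave 128 in p27delta51 and 32.4 in wild type, and E2f6 gave 331 against 160, although the mean over all probe sets of E2f6 went the other way. The CDK inhibitor genes Cdkn2b and Cdkn1c were at the floor in p27delta51, Cdkn2b at least 29.7-fold lower and Cdkn1c at 1.6 against 62.2. Cdkn2a, picked out after its values were seen, gave 7.0 against 172, at least 11.6-fold lower. Replication-dependent histone genes had 4 kept members, all lower in p27delta51, with H1f2 at 1038 against 3387 and H3c7 at 40.1 against 73.0.

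Interferon-response genes were higher in p27delta51. Of 27 kept members, 19 were at least 2-fold higher and 1 was at least 2-fold lower, and the median of 1.41 lay above all 10000 random lists. Usp18 and Oasl2 were at wild type signals of 4.6 and 0.4, at least 14.3-fold and 6.61-fold higher in p27delta51. Gbp2 was 2.21-fold lower, and Irgm1 gave 568 against 791. Genes of MHC class I and antigen presentation had a median of 0.45, above 9601 of 10000 random lists, with 1 of 10 members at least 2-fold higher.

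Chemokine, cytokine and NF-kB target genes had a median of -0.58, above 1 of 10000 random lists, with 9 of 23 members at least 2-fold lower and 4 at least 2-fold higher. Il6 and Tnfaip6 were at least 3.38-fold and 7.73-fold lower in p27delta51, whereas Ccl5 and Cxcl5 were at least 9.68-fold and 16.1-fold higher.

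Contractile and myofibroblast genes were lower in p27delta51, with 10 of 18 kept members at least 2-fold lower and 0 at least 2-fold higher. Their median of -1.13 lay below all 10000 random lists. Ankrd1 gave 13.7 in p27delta51 and 2307 in wild type, at least 156-fold lower, and Actg2, a smooth muscle actin gene, was 33.7-fold lower. Mylk gave 319 against 172. Fibrillar and basement-membrane matrix genes split, with 9 of 44 members at least 2-fold higher and 11 at least 2-fold lower. Their median of -0.25 lay above 11 of 10000 random lists, and with the upper-quartile filter its percentile was 1.38, inside the limits. Dcn, which encodes decorin, gave 21.3 against 2817, and Nid1, the nidogen 1 gene, was 35.2-fold lower, while Thbs2 and Mfap5 were 5.82-fold and 5.37-fold higher. Col2a1, the cartilage collagen gene, gave 22.1 against 826.

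TGF-beta and BMP, Wnt and Notch, and immediate-early genes were lower in p27delta51 in their medians, with members on both sides. TGF-beta and BMP genes had a median of -0.43, above 2 of 10000 random lists, with 12 of 31 members at least 2-fold lower and 6 at least 2-fold higher. Fst was 26.1-fold lower, Id2 gave 32.4 against 747, Bmp2 was at least 26.5-fold higher and Bambi 6.58-fold higher. Wnt and Notch genes had a median of -0.48, above 3 of 10000 random lists, with 9 of 28 members at least 2-fold lower and 5 at least 2-fold higher. Wnt5a was at least 28.0-fold lower and Sfrp1 21.5-fold lower, whereas Dll1 was 5.87-fold higher and Lrp5 at least 4.28-fold higher. In the authors' deposited table Dll1 and Lrp5 both carried a no-change call, at log2 ratios of 2.4 and 2.7. Immediate-early and serum-response genes had a median of -0.31, above 20 of 10000 random lists, and a percentile of 1.02, inside the limits, with the mean of all probe sets. Of 30 members, 7 were at least 2-fold lower and 5 at least 2-fold higher, with Fos and Dusp1 4.37-fold and 3.92-fold lower and Jun and Nr4a2 8.95-fold and 7.20-fold higher.

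Unfolded-protein and p53 target genes were lower in p27delta51. Of 31 kept genes of the unfolded protein and amino-acid stress list, 30 were lower, 6 of them at least 2-fold, and the median of -0.46 lay below all 10000 random lists. Ppp1r15a and Dnajb11 were 3.06-fold and 2.68-fold lower, and Shmt2 gave 1408 against 1325. The p53 target list had a median of -0.43, above 3 of 10000 random lists, with 7 of 26 members at least 2-fold lower and 3 at least 2-fold higher. Pmaip1, a death-promoting gene, was at least 18.2-fold lower and Fas gave 86.2 against 424, with a log2 ratio of -1.6 in the authors' deposited table, while Sesn1 and Gadd45a were 5.24-fold and 2.33-fold higher.

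Ribosomal protein and splicing factor genes showed small shifts, and glycolysis and hypoxia genes a positive median with members on both sides. Cytosolic ribosomal protein genes had a median of 0.33, above 9993 of 10000 random lists, with 36 of 39 members higher and 1, Rps27, at least 2-fold higher. In the authors' deposited table the log2 ratio of Rps27 was 0.6. Splicing factor genes had a median of 0.25, above 9956 of 10000 random lists, with 39 of 50 members higher, 0 at least 2-fold, and Snrpf at 1658 against 866. Glycolysis and hypoxia genes had a median of 0.44, above 9986 of 10000 random lists, with 6 of 25 members at least 2-fold higher, among them Egln3 (6.74-fold) and Pdk1 (3.85-fold), and 2 at least 2-fold lower, Pfkfb3 (at least 3.82-fold) and P4ha2 (4.42-fold). Against random lists not matched on signal, none of these 3 lists stood apart, with percentiles of 97.8, 94.7 and 99.1. With quantile normalization the ribosomal median was 0.062, at a percentile of 66.3, and with the mean of all probe sets the splicing median was 0.18, at a percentile of 90.4.

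**Figure D2:**
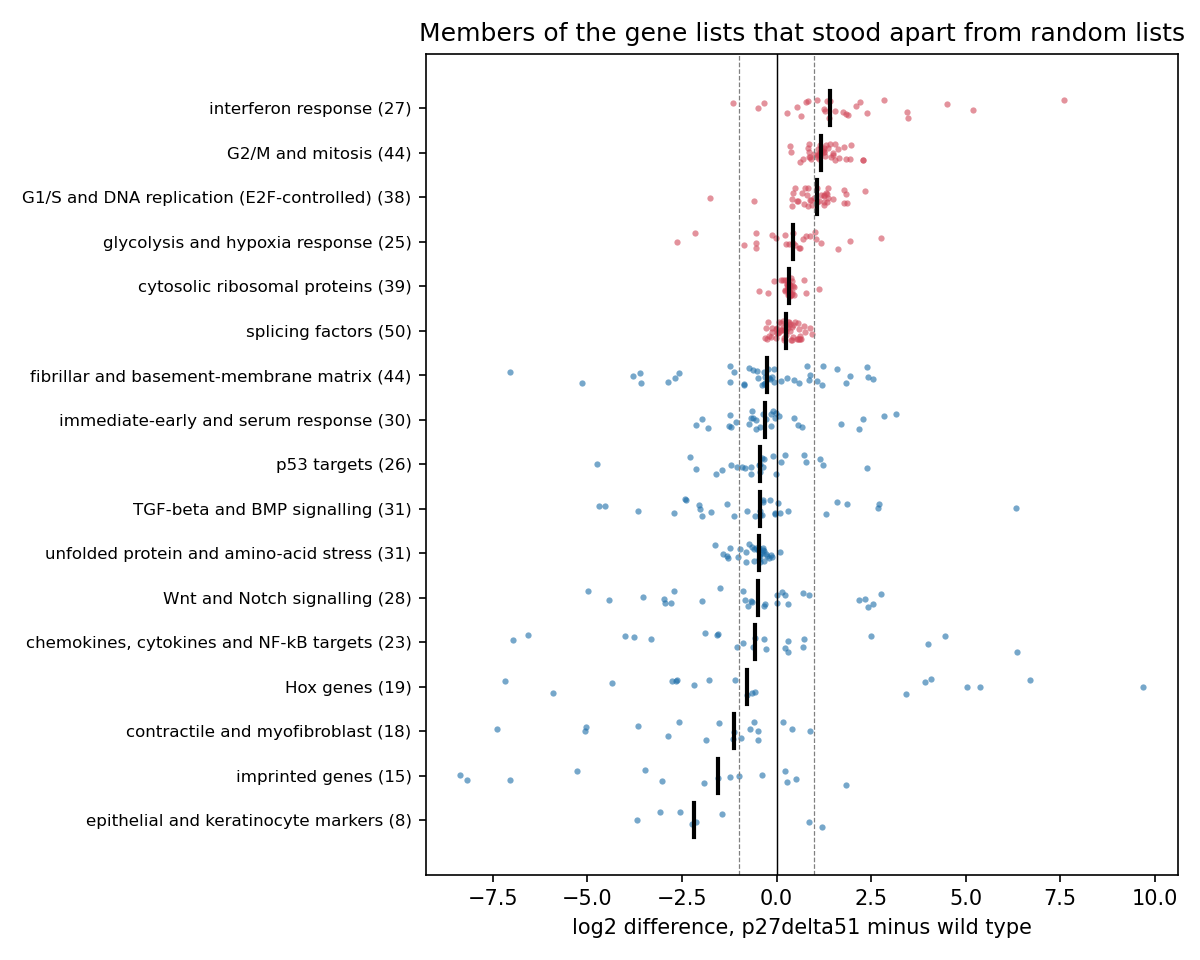
Log2 differences (p27delta51 minus wild type, x axis) of the kept members of the 17 lists that stood apart from random lists, 1 point per gene, with the number of members in brackets. Black bars mark list medians, from 1.41 for interferon-response genes to -2.18 for epithelial markers, and dashed lines mark a 2-fold difference.

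Hox genes, which mark position along the body and limb axes, split into genes far higher and genes far lower in p27delta51. Of 19 kept members, 7 were at least 2-fold higher and 9 at least 2-fold lower. The median of -0.79 lay below all 10000 random lists while the mean, with signals below the floor raised to it, was 0.57, and with the upper-quartile filter, which kept 6 members, the median was 5.21. Hoxd13 and Hoxd10 were at least 176-fold and 38.7-fold higher, and Hoxb2 and Hoxb6 at least 12.8-fold and 3.67-fold lower. Limb and body-region transcription factor genes had a median of 0.43, above 9902 of 10000 random lists, with 12 of 30 members at least 2-fold higher and 5 at least 2-fold lower. Besides Tbx4, Osr2 was 36.6-fold higher, whereas Osr1 gave 15.9 against 1015 and Foxf1 was at least 48.6-fold lower.

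Genes listed as imprinted, a term for expression from the copy of a single parent, were lower in p27delta51. From which copy they were expressed in these cells was not measured. Dcn, among the lower members, is also on the matrix and growth-arrest lists. Of 15 kept members, 10 were at least 2-fold lower and 1 at least 2-fold higher, and the median of -1.54 lay below all 10000 random lists. Peg3 gave 8.4 in p27delta51 and 2752 in wild type, and Meg3 gave 2.9 against 848. Igf2r was 3.58-fold higher, and Mest gave 2188 against 1545.

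**Figure D3:**
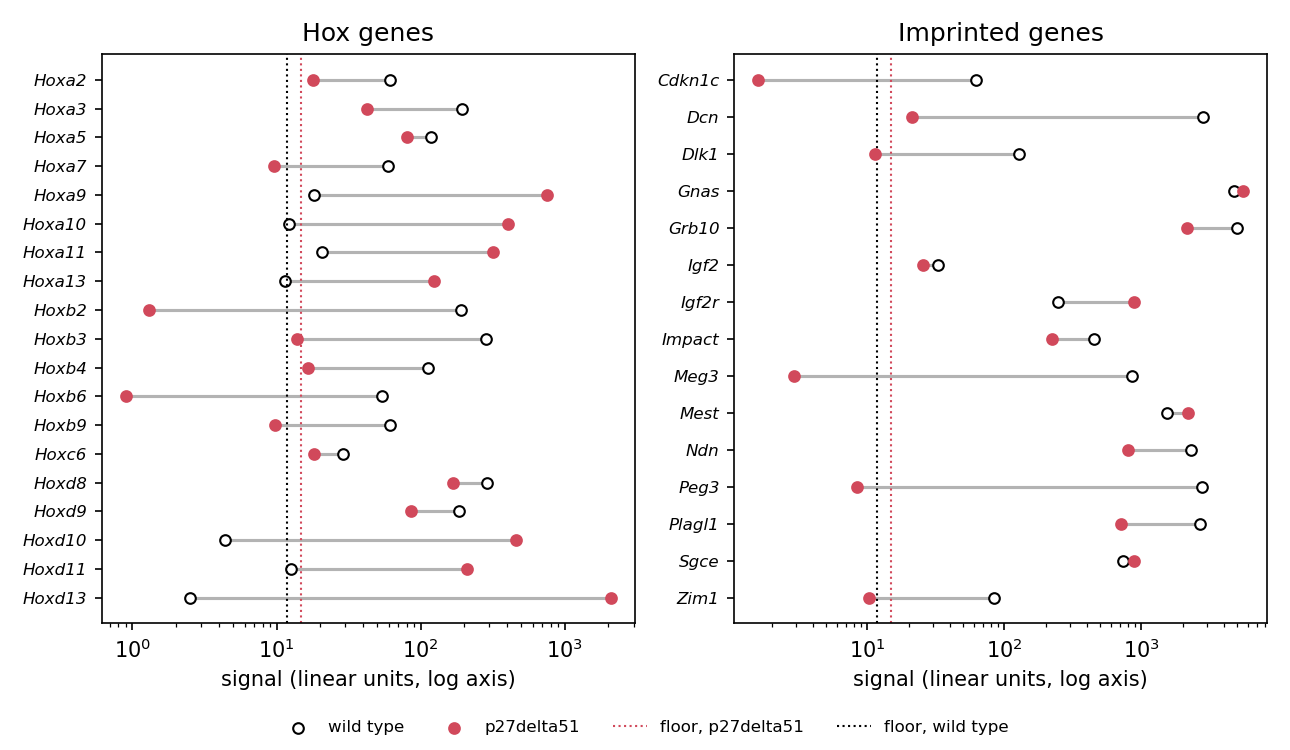
Signals of the kept Hox genes and imprinted genes on each array (x axis, linear signal units on a log axis, 1 row per gene), wild type as open circles and p27delta51 as filled circles, with dotted lines at the control floors of 14.8 and 11.8. Hoxd13 lies at 2.5 in wild type and 2079 in p27delta51, and Peg3 at 2752 and 8.4.

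Sex-linked genes and epithelial markers also differed between the arrays. Xist, the transcript of the inactive X chromosome, gave 876 in p27delta51 and 25.8 in wild type, 33.9-fold higher. The Y-linked genes Eif2s3y, Kdm5d and Uty were at least 28.7-fold, 14.4-fold and 9.60-fold lower in p27delta51. Epithelial and keratinocyte markers had a median of -2.18, above 1 of 10000 random lists, with 6 of 8 kept members at least 2-fold lower. The median was -1.92 with signals below the floor raised to it, -1.15 with log2 of the signal plus 32 and -0.94 with no filter. Krt19 was at least 11.9-fold lower while Epcam gave 60.7 against 26.4. In the authors' deposited table the log2 ratio of Epcam was 0.1. Lists of macrophage, endothelial, neural, muscle, adipocyte and chondrocyte markers did not stand apart, and their values follow in the closing observations. The chondrocyte list turned lower and stood apart with no filter, at a median of -0.69 and a percentile of 0.23, and with the upper-quartile filter, at a median of -3.72 over 5 genes, below all random lists. Housekeeping genes had a median of 0.13, above 7110 of 10000 random lists, with 0 of 16 members at least 2-fold apart. Actb gave 8004 in p27delta51 and 7270 in wild type. The 3' probe set of Gapdh gave 7629 and 5882.

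Genes that flank Cdkn1b on chromosome 6 did not stand apart as a list. Their median was 0.43, above 9845 of 10000 random lists, with 6 of 18 members at least 2-fold higher and 0 at least 2-fold lower. Mgp, a matrix Gla protein gene, was 40.4-fold higher in p27delta51 and Arhgdib 36.4-fold higher, while Strap and Ddx47 gave 1165 against 1558 and 399 against 467. On chromosome 3, where Crabp2, Rps27 and Gbp2 lie, the 547 kept genes had a median of 0.41, above all 10000 matched random lists, and 110 of them (20.1%) were at least 2-fold higher.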

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

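Both results were picked out because they lie in data outside the gene comparison. The spike-in control probe sets were brighter on the p27delta51 array, with a median log2 difference of 0.38 and 18 of 18 higher. They were read on 1 array per genotype and are not independent replicates. Among probe sets without a gene name here, 427 of 1836 above the brightness limit differed at least 2-fold, 286 higher and 141 lower in p27delta51.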

How the results depend on the processing

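The settings added after seeing the data were signals raised to the floor, ranking by mean log2 signal and the filters for the spread between probe sets. Without a replicate, list medians were held to the SD of matched random lists, counts to a factor of 1.5 and single genes to the spread between probe sets. With loess, median centring and quantile normalization both 2-fold counts stayed within that factor, and the share of higher genes among 2-fold genes was 50.2%, 50.3% and 52.3%, against 55.1%. These settings moved the median of all kept genes from 0.079 to 0.013, 0.0049 and 0.0425. No filter gave 2811 genes higher and 2587 lower, and the upper-quartile filter 559 and 461. A 1.5-fold threshold gave 2426 and 1774, and a 3-fold threshold 533 and 581. The size of these counts follows by construction, but the balance of directions does not. The share of higher genes was 57.76% at 1.5-fold and 47.85% at 3-fold, where lower genes were the more numerous. Log2 of the signal plus 32, which shrinks dim genes, gave 752 higher. All 17 lists that stood apart did so with loess, log2 of the signal plus 32 and signals raised to the floor. Median centring shifts every gene alike and cannot move a percentile. The lists that lost their place were splicing factors with no filter, the mean of all probe sets, the authors' deposited table and ranking by mean log2 signal, ribosomal proteins with quantile normalization and the authors' deposited table, immediate-early genes with the mean of all probe sets, and matrix genes with the upper-quartile filter. Against random lists not matched on brightness, splicing factors, ribosomal proteins and glycolysis and hypoxia genes lost their place. Epithelial markers kept 2 members with the upper-quartile filter, too few for a percentile, and Hox genes had 6 and a median of 5.21, turned in sign by the fewer genes. Lists that newly stood apart were cholesterol synthesis with no filter, quantile normalization and the authors' deposited table, chondrocyte markers with no filter and the upper-quartile filter, matrix proteases with the upper-quartile filter, and limb factors with the authors' deposited table.

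For the other medians that moved, the cause was not tested. With the mean of all probe sets, medians were 0.95 for G1/S, 0.067 for cyclins and CDKs, -0.0094 for translation factors, -0.37 for matrix, -0.10 for matrix proteases, -1.83 for contractile, -0.39 for chemokine, -2.20 for imprinted, -1.12 for Hox, 0.23 for Cdkn1b flanking, -0.63 for macrophage (3 genes), 0.98 for endothelial (3 genes) and -0.83 for muscle genes (5 genes), and E2f6 turned from 1.05 to -0.31. Cdkn1b, at 0.91 by its brighter probe set, was -2.18 with the mean of both probe sets, which differ in sign, and 0.6 in the authors' deposited table. With the upper-quartile filter they were -0.58 for matrix proteases, -0.48 for immediate-early, 1.02 for interferon, -0.75 for Wnt and Notch, -1.22 for imprinted, 0.27 for limb and -3.72 for chondrocyte genes (5 genes). The endothelial list at -2.40 and the muscle list at 1.90 then held 1 gene each, so these are values of single genes. With no filter they were -0.33 for Wnt and Notch, -1.002 for imprinted, 0.26 for limb, -0.94 for epithelial, -0.058 for neural, 0.32 for muscle and -0.69 for chondrocyte genes. With log2 of the signal plus 32 they were 0.93 for G1/S, 0.92 for interferon, -0.40 for chemokine, -0.31 for Wnt and Notch and -1.15 for epithelial genes. With quantile normalization they were 0.062 for ribosomal, 0.0315 for translation factor and -0.36 for matrix genes. Median centring gave 0.078 for oxidative phosphorylation, the authors' deposited table gave 0.1 for cyclins and CDKs and -0.5 for Hox genes, and ranking by mean log2 signal -0.64 for Wnt and Notch and -0.013 for chondrocyte genes. The spread between probe sets was 0.48 with no filter and 0.15 with the upper-quartile filter. Of 123 named genes at least 2-fold apart, 1, E2f6, turned in sign under an alternative. Most settings rescale the same signals, and the top genes were picked without bright probe sets of opposite sign, so few turns could occur. Dim signals limit the folds, since 137 of the 2-fold higher and 244 of the 2-fold lower genes had the dimmer array at or below its floor. No paired analysis was possible because each group holds 1 array and no test was made.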

Other observations

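The lists not yet described held genes on both sides. Oxidative phosphorylation genes had a median log2 difference of 0.15, above 9537 of 10000 random lists, with 0 of 58 at least 2-fold apart. Mitochondrial ribosomal, translation factor and proteasome genes had medians of 0.054, 0.13 and -0.14, above 5479, 7431 and 748 of 10000 random lists. Cholesterol synthesis genes had a median of 0.37, above 9939 of 10000 random lists, with Pmvk and Mvd 4.70-fold and 3.38-fold higher in p27delta51. Growth-arrest and FoxO target genes had a median of 0.34, above 9684 of 10000 random lists, with Gas2 18.8-fold higher and Gas6 26.2-fold lower. Oxidative stress and NRF2 target genes had a median of 0.25, above 9510 of 10000 random lists, with Nqo1 3.54-fold higher and Hmox1 2.25-fold lower. Lysosome and autophagy genes had a median of 0.11, above 6027 of 10000 random lists. Matrix protease and inhibitor genes had a median of -0.28, above 122 of 10000 random lists, with Mmp13 at least 33.5-fold higher and Timp3 27.8-fold lower. Cytosolic chaperone genes had a median of 0.0044 and a mean of -0.44, above 2910 of 10000 random lists in their median, with Hspb1 and Cryab 74.2-fold and 11.9-fold lower. Genes of the insulin-like growth factor axis had a median of 0.24 and a mean of -0.63, above 8349 of 10000 random lists in their median, with Igf1 7.95-fold lower.

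Among markers of other cell types, macrophage and leukocyte genes had a median of 0.49, endothelial genes -0.0099, neural and glial genes -0.34 and muscle genes -0.25. These lay above 8917, 3967, 378 and 1738 of 10000 random lists. With signals below the floor raised to it, adipocyte markers had a median of 0.26 and a mean of 0.16, and chondrocyte and osteoblast markers a median of 0.31 and a mean of -0.53, the medians above 8111 and 8201 of 10000 random lists. Within the chondrocyte list, Cnmd was at least 180-fold and Col2a1 37.4-fold lower in p27delta51, while Dmp1 was at least 17.6-fold and Mgp 40.4-fold higher. The folds of Col2a1, Hspb1, Igf1 and Nqo1 rest on a dimmer signal within 3 times of the floor and are approximate. Acan and Sox9, picked out after their values were seen, gave 46.5 against 613 and 33.6 against 314. The chondrocyte median was -0.69 with no filter and -3.72 over 5 genes with the upper-quartile filter, and the list then stood apart as lower. Erythroid and hepatocyte markers had 0 kept members. The Hox genes were ordered by paralog number, a grouping chosen after the values were seen. All 10 kept genes of paralog groups 2 to 8 were lower in p27delta51, all 6 of groups 10 to 13 were higher, and of group 9 Hoxa9 was higher and 2 were lower. Of 20 chromosomes with enough kept genes, chromosomes 5, 7, 11, 14, 16 and 18 had medians below all 10000 matched random lists, from -0.14 to -0.05. Besides chromosome 3, chromosomes 6, 9, 10 and X had high medians, above 9964, 9974, 9996 and 9963 of 10000 random lists. These lie past the upper limit used for lists, which was set for independent lists. With each of the low chromosomes cut into 3 equal parts in gene order, 17 of the 18 parts lay below the median of all kept genes. These chromosomes were picked for low medians, so most parts had to lie below and the split tests nothing further.

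Tests of the sex-linked and Cdkn2a patterns below were chosen after their values were seen, and those of chromosome 3 before their results were seen. Xist was higher and Y-linked genes lower on the p27delta51 array. By its probe sets Xist gave 536, 115 and 876 in p27delta51, against 0.5, 2.0 and 25.8 in wild type. Poor RNA on the p27delta51 array is argued against by the 3' over 5' signal ratios of Actb and Gapdh, of which the larger was 1.13 times that of wild type. Genes on X or Y made up 3.36% of the 2-fold genes, near their 3.23% share of all kept genes. With so few kept genes there, they could not have been the bulk of the 2-fold differences, so that test could not have come out otherwise. Cells of different sex on the 2 arrays remain a candidate explanation that cannot be told apart from other causes, since of 7 Y-linked genes above the floor in wild type 6 were at or below it in p27delta51, but only 3, Eif2s3y, Kdm5d and Uty, were over 3 times the floor in wild type. Sry, Uba1y and Zfy2 were barely above it, and Orly, near the floor at 31.1 in p27delta51 and 28.5 in wild type, failed the test as it was written. Signals within 3 times the floor were set aside as undecided only after that value was seen, so that test leaves the sexes of the cells open.

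Genes of chromosome 3 were higher in p27delta51, with a median of 0.41 over 547 genes, above all 10000 matched random lists. A trend with brightness is argued against, since after loess the chromosome lay 0.33 above the median of all kept genes (95% bootstrap interval 0.29 to 0.42). A few strongly different genes cannot move a median over 547 genes. On the chromosome 71.9% of genes lay above the median of all kept genes, which restates the shift and tests nothing further. An extra copy of the whole chromosome in p27delta51 cells predicted a shift in each of 3 equal parts of the gene order, and the lowest lay 0.29 above the median. The test asked only for a small shift in each part, not for the size that an extra copy would give. Any shift spread along the chromosome would pass it, so such a copy stays a hypothesis. DNA was not analysed here and GC content was not tested. Of the other chromosomes, 6 had low medians, and chromosomes 6, 9, 10 and X lay past the upper limit used for lists.

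Cdkn2a and Cdkn2b were at the control floor in p27delta51, whereas Mtap, their kept neighbour on the same chromosome, was 4.89-fold higher there. For probe sets that do not work, the lower wild type signal of Cdkn2a and Cdkn2b was 14.6 times the floor. Both genes were picked as far lower in p27delta51 and so had to be bright in wild type. That test could not have come out otherwise. Silencing of the wider neighbourhood needs 2-fold lower values in the next expressed genes on both sides. Mtap had a log2 difference of 2.29 with all 4 of its probe sets higher. Its higher signal was part of the pattern when the test was chosen, so it restates the pattern and tests nothing further. Tusc1 and Caap1 on the other side were at -0.19 and -0.39, short of 2-fold lower, which argues against silencing that reaches them. A deletion of the segment with both genes remains possible, as the highest p27delta51 signal among their probe sets was 7.0. It cannot be told apart from loss of expression without a deletion, because RNA alone gives the same reading for both.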
